A study of Oryctolagus cuniculus with 8 samples.

How the data were processed

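Forebrain RNA of 8 preterm rabbit pups, 4 given saline and 4 given dexamethasone, was measured on Agilent 2-colour rabbit arrays of design 020908 with 45220 spots, of which 43803 were not controls and held 43603 probes. The deposited scanner files hold spot intensity (mean, median and local background per dye) and processed signal, made with Agilent Feature Extraction, version 10.7.3.1 per the submitters' processing notes and 11.0.1.1 per the file headers. The processed signal was spatially detrended and dye-normalised, with a floor for dim spots, per the file headers. Each file was deposited identically for the 2 samples of its array, so that 4 arrays held the 8 samples. Each sample was read from the channel of its own dye, as per the labels. Both channels of an array held samples of the same group, and the slide and the scan day, per the file headers, each held 1 group only, so a slide or scan term could not be fitted.

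The deposited series table gives a signal per spot. It matched the median minus the background median intensity of the sample's own channel divided by a constant per column, within 0.1% for 100% of the listed values, and listed no control spot and no spot whose median was at or below 2 times its background. The median of each of the 8 columns is 1, so its scale and direction are known, and no centring beyond that was found. The genome build named in the file headers is oryCun2.

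Probes were named from the array's own annotation and from a RefSeq gene table of the assembly mOryCun1.1, which gave 1 symbol to 22615 probes and none to 20988. Of the 548 genes in the fixed lists, 360 had a probe. Accessions were matched without versions, and transcripts with no symbol were kept under the array's identifier.

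Intensities were corrected with normexp (offset 50) on mean and background median signals, normalised by loess within arrays with control and outlier spots at weight 0, and by Aquantile between arrays, and split into log2 values per channel. Outlier spots were left out, from 197 in dexamethasone 3 to 3022 in saline 4, and 0 spots were saturated. Spots of a probe were averaged. Probes were kept if well above background in at least 4 of 8 samples, which left 23165, and the probe with the highest mean stood for a gene. A gene needed at least 3 values in each group. This last rule was chosen after a first fit over genes with all 8 values had been seen, and both are given. Among the 4063 genes with 2 or more kept probes, the differences of the first 2 probes correlated across genes with Pearson's r = 0.453 and Spearman's rho = 0.465, where genes are not independent replicates.

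Dexamethasone was compared with saline with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with dye as a covariate and array as a random block at the consensus correlation of 0.239, and p-values were adjusted by the Benjamini-Hochberg method over 11252 genes. The 21 gene lists were tested 2-sided with limma's camera (preset correlation 0.01) on values whitened for the array correlation, with missing values at their fitted value, and adjusted over the lists by the Benjamini-Hochberg method. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance the same way without comparison with other genes, were run beside it. A list score per sample was the mean deviation of its members from their gene means, compared by a 2-sided exact permutation test over the 70 divisions of 8 samples. Where a probe was not well above background in any sample of a group, the fold was taken against a floor. It is the bright group's mean against the dim group's mean of, per sample, the higher of the probe's own value and the floor. The floor is the lowest value of any probe well above background. For the features higher with dexamethasone the floor did not act, so their fold is the fitted estimate and not a bound.

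The 21 lists, their tests, the rule for named genes and all alternatives but the last 2 below were fixed before the data were examined. The rule named up to 8 rises and 8 falls among genes with a symbol past an adjusted p of 0.05 whose groups do not overlap, for each list the 2 members with the smallest p, and genes fixed by name where measured, among them NR3C1, FKBP5, MBP, GFAP and PDGFRA. Not every gene that the rule named is printed. TSC22D3, MAL, CLDN11, CCNB1, MKI67, CCND2, FOS, HBB2, NUSAP1 and CKS2 were named after their values were seen, as were the called transcripts with no symbol. Alternatives covered background correction, normalisation, the filter on dim probes, the probe rule, the array block, the dye term, the replicate number as a block, the deposited table, the eBayes prior, thresholds, each sample and each array left out, and, chosen after the data were seen, genes with all 8 values and outlier spots kept. The added lists and the splits of the samples followed the first fit.

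The fit was tested on simulated data with the genes, variances and array correlation of this comparison. Over 11252 genes, it recovered 34% of 50 genes changed by 0.5 log2 units, 92% of 50 changed by 1, and 100% of 50 changed by 2 and of 50 changed by 3, with 13 false calls among 176 (7.39%), and estimated an array correlation of 0.166 where 0.239 had been set. A shift of -0.25 put into the cell cycle list was found as -0.26, with 0 other lists called. Noise was drawn separately for each gene, so the simulation held no correlation between genes. It therefore cannot show how often camera with the preset correlation calls lists wrongly where genes are correlated.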

Results

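The series measured gene expression in the forebrain of New Zealand rabbit pups that had been delivered preterm by Caesarean section at day 29 of a 32-day gestation and were sampled at postnatal day 14. Pups in 1 group received the synthetic glucocorticoid dexamethasone intramuscularly, 0.25 mg/kg 2 times a day for at most 5 days, and pups in the control group received saline. The series' title gives the question as whether glucocorticoids given after birth hold back myelination. The groups held 4 saline and 4 dexamethasone samples, named as biological replicates in the design text. RNA was hybridised to 4 Agilent rabbit arrays, each carrying 2 samples of the same group, the odd-numbered sample in Cy3 and the even-numbered sample in Cy5. The share of spots well above background differed by dye and, within each dye, was lower in saline without overlap. In Cy3 it was 42.5% (saline 1) and 39.1% (saline 3) against 48.8% (dexamethasone 1) and 47.7% (dexamethasone 3). In Cy5 it was 52.9% (saline 2) and 59.7% (saline 4) against 64.3% (dexamethasone 2) and 62.9% (dexamethasone 4). Outlier spots numbered 932 to 3022 in the saline samples and 197 to 509 in the dexamethasone samples. Expression was compared for 11252 genes or transcripts, 6419 of them with a gene symbol, as log2 normalised intensity. The number of arrays limits the precision, and the median SE of a log2 difference was 0.13.

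The saline arrays lay on slide 1 and were read in scan 1, and the dexamethasone arrays lay on slide 2 and were read in scan 2. With 0 slides holding both groups, slide and treatment cannot be told apart in any comparison that follows. The 10 spike-in control probes, which report RNA added during labelling and not rabbit transcripts, were all lower on the dexamethasone arrays after normalisation, by between -0.59 and -0.30 log2 units with a median of -0.44. Their SD within groups ran from 0.23 to 1.88 in saline and from 0.11 to 1.74 with dexamethasone, for most probes more than the difference. Each of these SDs pools Cy3 and Cy5 samples and so includes any difference between the dyes, while both groups held both dyes. Across the 10 probes the SD of the difference was 0.10, so the shift was similar from probe to probe. All were read on the same arrays, so they are not independent measurements.

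The comparison of dexamethasone with saline called 7 genes or transcripts at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 2 higher and 5 lower with dexamethasone, and in all 7 the values of the groups did not overlap. The only called gene with a symbol was NT5C3B, which encodes a cytosolic nucleotidase and rose 3.65-fold, from a log2 intensity of 8.40 ± 0.07 (SD, n = 4) in saline to 10.27 ± 0.42 (SD, n = 4) with dexamethasone. Its log2 difference was 1.87 (SE 0.20, limma with Benjamini-Hochberg adjusted p = 0.0245), and it was well above background in 2 of 4 saline and 4 of 4 dexamethasone samples. The size of the rise depended on the processing, with a log2 difference of 3.81 with the processed signals and 1.40 to 3.81 over all alternatives. The NT5C3B probe (gene ID 100341892) lies on chromosome 19 between positions 42728608 and 42728745 of oryCun2. The other transcript that rose, EB381782, was not well above background in any saline sample. It was 3.31-fold higher with dexamethasone as fitted, an estimate and not a bound (limma with Benjamini-Hochberg adjusted p = 0.0232).

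Of the 5 transcripts that fell, the probe A_04_P037452, which has no gene in the array's annotation, had the smallest adjusted p, with a log2 difference of -1.46 (SE 0.11, limma with Benjamini-Hochberg adjusted p = 0.00747). The transcript EB378866 was not well above background in any dexamethasone sample and was at least 2.71-fold lower (limma with Benjamini-Hochberg adjusted p = 0.0245). At an unadjusted p under 0.05 the fit gave 1544 genes, 662 higher and 882 lower, where 563 are expected by chance. Of 34 splits of the samples, 3 gave as many, the real split among them, with 2092 in the highest other. The 2 other splits that keep arrays whole gave 198 and 234. The groups did not overlap for 1488 genes, 13.2% of those tested, where chance gives 2.86% if all 8 samples are interchangeable, which samples that share arrays within groups are not. No gene was called when any dexamethasone sample was left out, 12 were called without saline 2, and 0 were called in a fit of 2 array means against 2.

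Genes of the cell cycle fell as a group with dexamethasone. The median log2 difference of the 19 tested members was -0.25, with 18 members below 0 and 1 above (camera in limma, preset correlation, Benjamini-Hochberg adjusted p = 1.1e-07 over 21 lists). The call was lost when the correlation between genes was estimated from the data (limma camera, Benjamini-Hochberg adjusted p = 0.0977 with an estimated correlation). The rotation test fry, which asks whether the members move on balance in the same direction, gave a limma Benjamini-Hochberg adjusted p = 0.00491. No member passed over all genes tested, and 5 fell when adjusted over the list alone. These were UBE2C, a ubiquitin-conjugating enzyme of mitosis (-0.60, SE 0.10), the mitotic cyclins CCNB2 (-0.52, SE 0.10) and CCNB1 (-0.39, SE 0.10), the proliferation marker MKI67 (-0.45, SE 0.12) and the G1 cyclin CCND2 (-0.62, SE 0.19). UBE2C went from 10.19 ± 0.15 (SD, n = 4) to 9.60 ± 0.19 (SD, n = 4), and all 5 of its kept probes were lower, by between -0.61 and -0.45. The mean of the list lay between 0.09 and 0.21 log2 units above the gene means in the saline samples and between 0.10 and 0.20 below them with dexamethasone. An exact permutation test of that score gave p = 0.0286, the smallest that 4 samples against 4 allow, and 0.60 after Benjamini-Hochberg adjustment over the lists. That test has the same limit of shared arrays. The list was not called under scaling to the 75th percentile, where its median was -0.53.

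**Figure D1:**
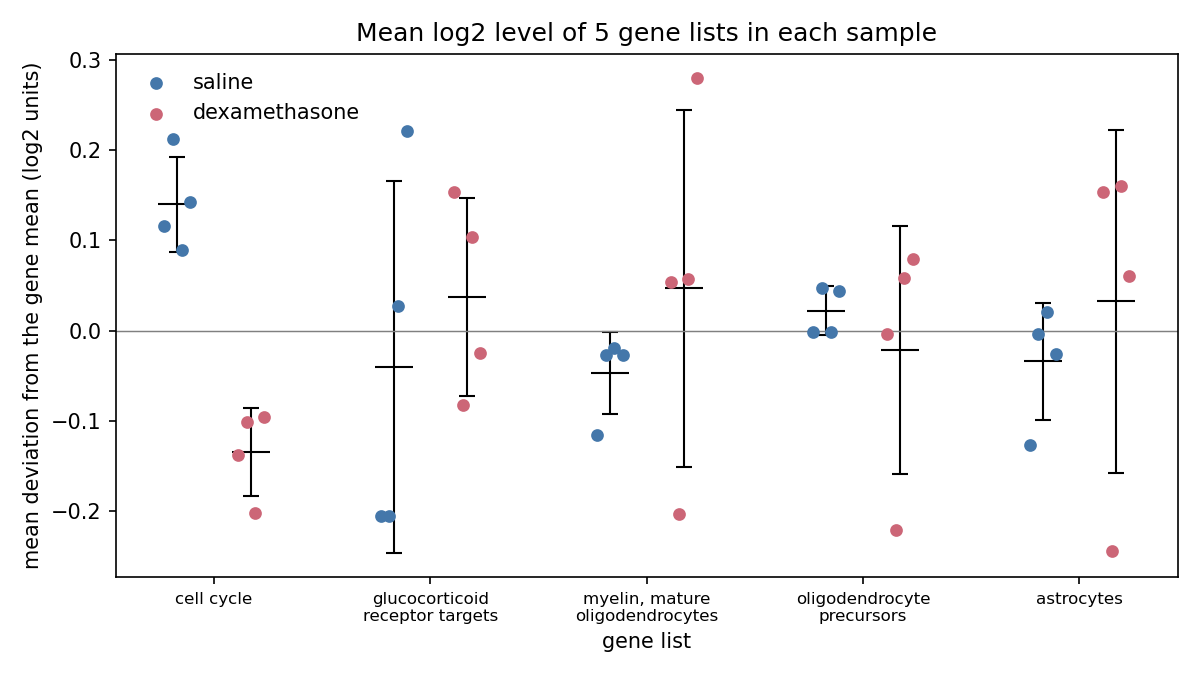
Mean log2 level of 5 gene lists in each of the 8 samples, as deviation from each gene's mean over the samples, with 4 saline and 4 dexamethasone points per list and the group mean ± SD in black. The cell cycle scores of all 4 dexamethasone samples, from -0.20 to -0.10, lie below those of all 4 saline samples, from 0.09 to 0.21, and the groups overlap for the other 4 lists.

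Known targets of the glucocorticoid receptor were not called as a list. The list holds 35 genes, of which 16 were tested. Of the 16 tested members, 0 rose and 0 fell over all genes tested or adjusted over the list alone, 10 lay above 0 and 6 below, and the median log2 difference was 0.04 (camera in limma, Benjamini-Hochberg adjusted p = 0.639). Several members, DDIT4 among them, were well above background in only 1 or 2 of 4 saline samples but in 4 of 4 dexamethasone samples. Their differences rest on saline values near background, so the test says little about them. The members with the smallest p were TXNIP, an inhibitor of thioredoxin, with a difference of 0.64 (SE 0.29, limma with Benjamini-Hochberg adjusted p = 0.368) but -0.07 at its other probe, and DDIT4, an inhibitor of mTOR signalling, with 0.48 (SE 0.23, limma with Benjamini-Hochberg adjusted p = 0.376). TSC22D3, the glucocorticoid-induced leucine zipper, differed by 0.19 (SE 0.10, limma with Benjamini-Hochberg adjusted p = 0.402), with no overlap between groups, as for 13.2% of all genes tested. It was well above background in 2 of 4 saline and 4 of 4 dexamethasone samples. FKBP5, a co-chaperone of the receptor, was well above background in only 1 of 8 samples and was not tested. The receptor gene NR3C1 itself stood at 8.90 ± 0.12 (SD, n = 4) in saline and 8.81 ± 0.13 (SD, n = 4) with dexamethasone, a difference of -0.10 (SE 0.12, limma with Benjamini-Hochberg adjusted p = 0.705), and its other 2 probes differed by -0.36 and -0.14. With saline 3 and 4, which shared an array, left out, the target list passed with a median of 0.20 (camera in limma, Benjamini-Hochberg adjusted p = 0.00149, and adjusted p = 0.424 with an estimated correlation), where the adjusted p over all alternatives ran from 0.00149 to 0.962. Without these samples 1 saline array was left, and the fitted correlation within arrays was negative, at -0.38.

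Genes of myelin and mature oligodendrocytes, the cells the series' title concerns, were not called as a list. The list holds 33 genes, of which only 16 were tested. Of the 16 tested members, 12 lay above 0 and 4 below, with a median log2 difference of 0.15 (camera in limma, Benjamini-Hochberg adjusted p = 0.401). None passed over all genes tested, and 1 fell when adjusted over the list alone. This was GJB1, the gap junction protein connexin 32, which differed by -0.67 (SE 0.15, limma with Benjamini-Hochberg adjusted p = 0.226), and both of its probes were lower. The pteridine reductase QDPR differed by 0.45 (SE 0.14, its other probes 0.06 to 0.33) and the myelin and lymphocyte protein MAL by 0.51 (SE 0.16). In both cases the groups did not overlap, as for 13.2% of all genes tested. The tight junction protein CLDN11 differed by -0.46 (SE 0.17). MAL was well above background in 2 of 4 saline and 4 of 4 dexamethasone samples. MBP had no probe named for it in the array's annotation.

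**Figure D2:**
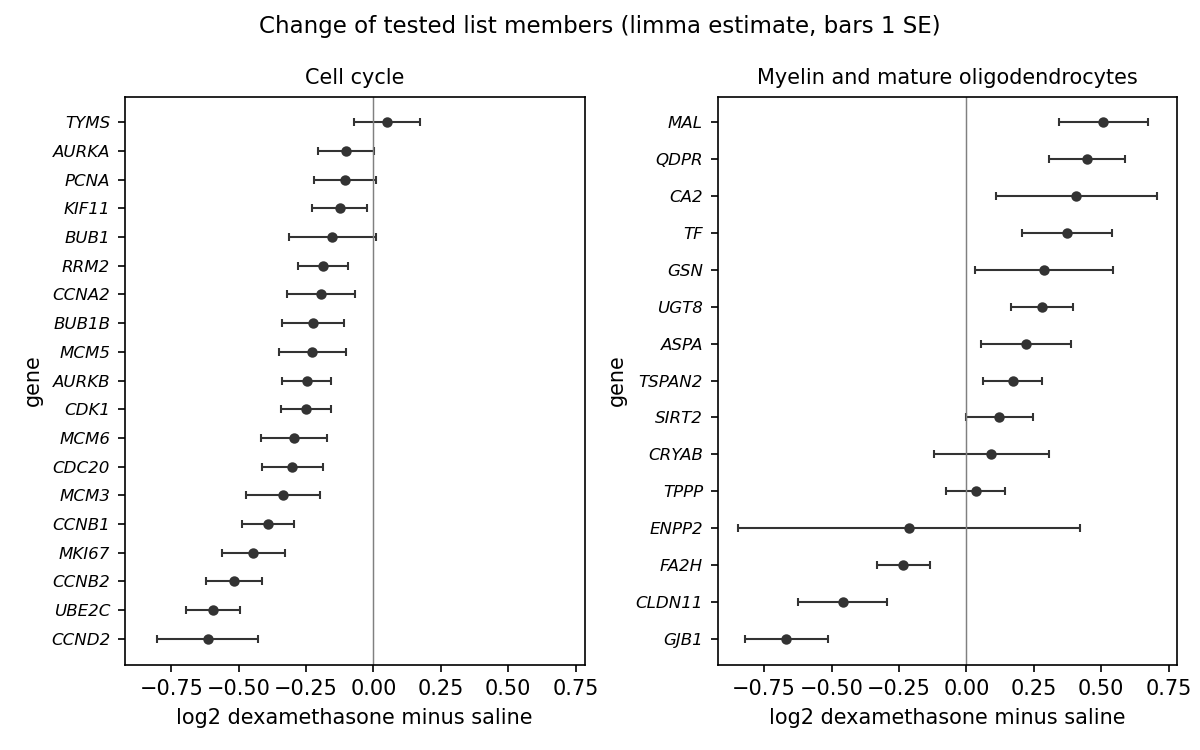
Log2 difference of dexamethasone minus saline for tested members of the cell cycle list and of the list of myelin and mature oligodendrocytes, as the limma estimate with a bar of 1 SE. Of the cell cycle members 18 of 19 lie below 0, while most of the myelin members drawn, which leave out 1 of the 16 tested, lie above 0.

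Markers of oligodendrocyte precursors and premyelinating cells were not called as a list. Of 10 tested members, from a list of 24, 5 lay on each side of 0, 0 rose and 0 fell by either adjustment, and the median was -0.00028 (camera in limma, Benjamini-Hochberg adjusted p = 0.866). BCAS1, a marker of newly formed oligodendrocytes, differed by -0.43 (SE 0.22) and GPR17, a receptor of committed precursors, by 0.16 (SE 0.14). PDGFRA had no probe named for it. Astrocyte markers were not called as a list either, with 8 of 12 tested members, from a list of 26, above 0 and a median of 0.04 (camera in limma, Benjamini-Hochberg adjusted p = 0.639). The sodium pump subunit ATP1B2 differed by -0.52 (SE 0.16) without overlap between groups, as for 13.2% of all genes tested, and the lipid carrier APOE by 0.46 (SE 0.17). GFAP, the intermediate filament of astrocytes, was well above background in 3 of 8 samples and was not tested.

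Of the 21 lists the cell cycle list was the only list called, and with an estimated correlation none was, and no member of any list passed over all genes tested. In the list of endothelial cells and pericytes (10 tested, median 0.18) ABCB1, a drug efflux pump of the blood-brain barrier, rose when adjusted over the list alone, from 9.67 ± 0.24 (SD, n = 3) to 10.43 ± 0.16 (SD, n = 4), and ANGPT2, a vessel growth factor, differed by 0.29 (SE 0.13). That list passed without dexamethasone 2, with a median of 0.28, but not when the correlation was estimated (limma camera, Benjamini-Hochberg adjusted p = 0.490 with an estimated correlation). In the list of blood cells (7 tested, median -0.24) the neutrophil protein S100A9 fell when adjusted over the list alone, from 10.55 ± 0.14 (SD, n = 4) to 9.62 ± 0.13 (SD, n = 4), with an adjusted p over all genes of 0.0696 (limma, Benjamini-Hochberg). The B cell marker MS4A1 differed by -0.36 (SE 0.12). Immediate early genes, which respond to stimulation of cells, had a median of -0.31 over 10 members, with ZFP36 at -0.36 (SE 0.15) and JUN at -0.62 (SE 0.27), and with saline 3 and 4 left out JUN was -0.17 and the list median -0.06. The list passed without saline 1, at -0.32, without dexamethasone 1, at -0.26, and without array 1 or array 3. None of these calls held with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p from 0.578 to 0.874), and over probes above background in all 8 samples the median was 0.04. In the inflammation list (12 tested, median -0.12) CXCL8 differed by -0.38 (SE 0.12), with its 3 probes between -0.38 and 0.00, and PTGS2 by -0.83 (SE 0.33), which was -0.21 with saline 3 and 4 left out. Respiratory chain genes (19 tested, median 0.14) had 16 members above 0, among them ATP5F1B with 0.32 (SE 0.13) and UQCRC1 with 0.31 (SE 0.13). Genes of cholesterol and fatty acid synthesis (14 tested, median 0.10) had 12 members above 0, among them ELOVL1 with 0.27 (SE 0.11, its other probes -0.14 to 0.21) and SQLE with 0.23 (SE 0.11).

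Neuronal lists were not called. The neuron list (9 tested, median 0.12) held SYT1, a calcium sensor of synaptic vesicles, with -0.33 (SE 0.13) and RTN1 with 0.22 (SE 0.16). The glutamatergic list (8 tested, median -0.07) held the receptor subunit GRIA3 with -0.58 (SE 0.19). The GABAergic list (13 tested) had a median of 0.05 but a mean of -0.08, the direction of its test, with the peptide NPY at -0.45 (SE 0.17). The list for choroid plexus and ependyma (11 tested, median 0.16) held KL with -0.50 (SE 0.16) and DNAI1 with 0.46 (SE 0.19). Growth factor and morphogen signals (13 tested, median -0.15) held IGF1 with -0.35 (SE 0.13) and BMP2 with 0.30 (SE 0.12). Meninges and collagen matrix (16 tested, median 0.04) held SLC6A13 with 0.52 (SE 0.26) and PTGDS with 1.18 (SE 0.72), which was 0.49 without saline 1. Heat shock and endoplasmic reticulum stress (13 tested, median 0.13) held HERPUD1 with 0.25 (SE 0.09) and XBP1 with 0.25 (SE 0.16, its other probes -0.03 to 0.29). Microglia and macrophages (8 tested, median -0.02) held CD14 with -0.39 (SE 0.30), which was 0.19 with saline 3 and 4 left out, and CD68 with -0.15 (SE 0.13). Ribosomal proteins (22 tested, median 0.02 and mean -0.03) held RPS13 with -1.35 (SE 0.60) and RPL3 with 0.37 (SE 0.24), which was 0.04 without saline 1. RPS13 stood at 11.95 in saline 3 and 10.93 in saline 4, against 9.59 in saline 1 and 9.12 in saline 2. Its difference was -0.73 without saline 3 and ran from -2.39 to -0.24 over all alternatives. Components of glucocorticoid and mineralocorticoid signalling (7 tested, median 0.10) held NR3C2, the mineralocorticoid receptor, with 0.18 (SE 0.11) and CRH with 0.22 (SE 0.15), which was -0.03 with saline 3 and 4 left out. The adjusted p of the uncalled lists, from camera in limma with Benjamini-Hochberg adjustment, ran from 0.171 to 0.905.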

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

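Leaving out saline 3 and 4 was planned, the other tests of the cell cycle list were chosen after its shift was seen and before their own results, and the reading of the neural progenitor list as undecided was settled after its value was seen, as was the reading of the splits by whole arrays. Cell cycle genes were lower with dexamethasone (median log2 difference -0.25), a call that was lost with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p = 0.0977). Probe GC content and probe position along the transcript are argued against, since both trends over all genes were small (SD 0.03 and 0.02) and removing them left the median at -0.23 and -0.25, and signal level likewise, since 0.01% of 10000 random lists matched on signal level reached a median as low. It also did not rest on the single saline array of saline 3 and 4, without which it was -0.32, and of 34 splits of the 8 samples only the real split, 1 of 34, gave a camera p as small (5.22e-09 against 1.07e-08 for the next), but samples share arrays within groups and the 3 splits into whole arrays are too few for a share under 0.05. That next split set saline 1, 2 and 3 with dexamethasone 1 against the others, and so kept most of the real grouping. A lower share of dividing cells is a candidate explanation: 48 further cell cycle genes, listed before their values were seen, were lower too (camera in limma, unadjusted p = 6.73e-06, Benjamini-Hochberg adjusted p = 0.101 with an estimated correlation, median -0.13, 38 of 48 below 0), while 9 markers of neural progenitors and immature neurons went both ways, 3 above 0 and 6 below (camera p = 0.961), which leaves open whether progenitors were fewer. Slide and scan remain open, because 0 slides held both groups and the cause cannot be told apart from treatment. The further cell cycle genes were read on the same slides, so their shift cannot tell fewer dividing cells from a slide effect.

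Between the groups 7 genes or transcripts were called, and 2 of 34 splits of the samples, the real split among them, called as many, while the 3 splits into whole arrays are too few for a share under 0.05. The split with the most calls, 129, set saline 1, saline 3, dexamethasone 2 and dexamethasone 3 against the others, and took 1 sample of each array. It follows the dyes except on the array of dexamethasone 1 and 2. It compares channels within arrays, at a fitted array correlation of 0.597 against 0.239 for the real split. The other fitted splits that took 1 sample of each array called 0 to 6 genes, and the cause of the 129 calls was not tested. The splits that kept arrays whole but mixed the groups called 1 and 0 genes.

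Single samples stood apart from the other samples of their group in 11 of 131 groups of 4 values examined, where about 1 in 20 is expected by chance. PTGDS was at 13.31 in saline 1 against 15.47 to 15.90 in the other saline samples. IGF1 was at 8.58 in saline 1 against 8.91 to 8.97, and the myelin list's score was at -0.12 in saline 1 against -0.03 to -0.02. In saline 2, S100A9 was at 10.34 against 10.61 to 10.63, CXCL8 at 8.82 against 8.99 to 9.02, and BMP2 at 9.89 against 9.60 to 9.61. In dexamethasone 1, XBP1 was at 10.92 against 10.46 to 10.54, and SYT1 at 11.29 against 11.49 to 11.52. In dexamethasone 3, NPY was at 13.29 against 12.79 to 12.86, GPR17 at 9.33 against 9.04 to 9.09, and CD68 at 8.49 against 8.79 to 8.85.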

How the results depend on the processing

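The cell cycle list kept its direction under every alternative run, with a median between -0.53 and -0.20, and camera in limma with the preset correlation called it in 27 of 28 refits. The exception was 75th percentile scaling (-0.53), which put the median of all genes at -0.24 against 0.02; with an estimated correlation the call was lost (-0.25), as it was in all 28 refits. The lists of myelin, oligodendrocyte precursors and astrocytes were called under no alternative. The glucocorticoid target list was called only with array 2 left out (0.20), and not with an estimated correlation as well. Uncalled medians changed sign in 55 of the 651 list values.

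The count of called genes, 7 (2 higher, 5 lower), depended on the processing. It was 14 with the processed signals (6 higher, 8 lower), 7 under quantile normalisation (4 higher, 3 lower), 2085 under 75th percentile scaling (44 higher, 2041 lower), 2 with no filter on dim probes and 3 with probes above background in all 8 samples. It was 11 with the mean of probes, 23 with no array block, 0 with array means, 20 in the separate-channel fit and 15 with no dye covariate. At an adjusted p under 0.10 it was 21, and at an unadjusted p under 0.05 with 1.5-fold, applied to genes only, 232. Leaving out a sample gave 0 to 12. Leaving out array 1 gave 2215, array 2 gave 216, array 3 gave 0 and array 4 gave 1. Without array 1 or 2 a single array stood for saline and the fitted array correlation was negative (-0.32 and -0.38), which narrows the errors. The more negative correlation, without array 2, went with the smaller of these 2 counts. The cause of these shifts in the count, and of the others, was not tested.

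Of the 17 lists other than those of glucocorticoid targets, myelin, oligodendrocyte precursors and astrocytes, 1 was called, the cell cycle list. The count was 4 under 75th percentile scaling (respiratory chain 0.82, neurons 0.66, heat shock 0.55, ribosomal proteins 0.53, none with an estimated correlation). It was 2 without array 1 and without array 3, 0 with an estimated correlation, and 1 to 2 on leaving out a sample. With the deposited table the median of all genes was 0.13. Among 45 named genes 1256 of 1309 values kept their side of the threshold, 45 gained a call, and NT5C3B lost its call in 8. Of the values that kept their side, 20 changed sign. Samples that share a number showed no sign of pairing: their deviations from the group means correlated between -0.13 and 0.10, and 0 of 4 matched best with their own number. With 2 arrays in each group and 1 dye per number, this check cannot exclude a pairing. With the replicate number as a block 5 genes were called and no list call changed. A slide or scan block could not be fitted. Genes with all 8 values and kept outlier spots, chosen after the data were seen, gave 6 genes each. Signal over background limits the dim genes: FKBP5 and GFAP were not tested.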

Other observations

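The added lists, the split counts of dim features and the comparisons within saline were chosen after the first fit had been seen. Of the genes and transcripts tested, 13 were well above background in all 4 dexamethasone samples and in no saline sample, and 6 the reverse. Named among them after their values were seen were DOCK1, 4.43-fold higher with dexamethasone as fitted (limma with Benjamini-Hochberg adjusted p = 0.102), and SLC12A1, at least 2.53-fold lower (limma with Benjamini-Hochberg adjusted p = 0.115). The 19 such features compare with a median of 1 over the other 34 splits of the samples, and 5 of all 35 splits reached as many, the most being the split by dye with 535. Within each dye the dexamethasone samples, on a slide of their own, also had more spots well above background than the saline samples. A difference in detection between slides therefore cannot be told apart from treatment in these counts.

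Within saline, the samples of array 2 stood higher in immediate early genes, with list scores of 0.34 in saline 3 and 0.57 in saline 4 against -0.13 in saline 1 and -0.18 in saline 2. The inflammation list followed (0.22 and 0.42 against -0.08 and -0.07), as did the glucocorticoid receptor targets (0.03 and 0.22 against -0.21 and -0.21). FOS, a transcription factor induced by cell stimulation, had an SD of 1.36 in saline and 0.22 with dexamethasone (n = 4 each). The beta globin HBB2 had an SD of 1.47 in saline (n = 3) and 0.38 with dexamethasone (n = 4).

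The lists added after the first fit gave no further call beside the cell cycle genes (camera in limma, Benjamini-Hochberg adjusted over 5 lists), and the further cell cycle list lost its call at adjusted p = 0.101 with an estimated correlation. Interferon response had a median of -0.14 over 6 genes (adjusted p = 0.295), glycolysis of 0.12 over 12 (adjusted p = 0.295) and proteasome of 0.05 over 24 (adjusted p = 0.316). Of the 48 further cell cycle genes 0 passed over all genes and 0 adjusted over the list alone, with the smallest p for NUSAP1 (-0.77, SE 0.16) and CKS2 (-0.59, SE 0.14). Of the 9 markers of neural progenitors and immature neurons, 2 are also in a fixed list.

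Saline 3 and 4 lay a median distance (robust SD of log2 differences) of 0.313 from the other samples, against 0.259 between other samples on different arrays. On the first principal component (35.7% of variance) they lay at -26.4 and -21.4, and the other 6 samples at -2.47 to 19.1. The tests set for this asked whether the distance fell within the range of the others, which it already did (0.208 to 0.365), and so decided nothing. The distance was 0.584 with the processed signals (range of the others 0.326 to 0.674) and 0.313 over probes free of outlier spots, and the cause of the separation stays open. The reading of these tests as undecided was adopted after the values were seen. The channels of array 2 differed little at low signal, with a robust SD of 0.03 in the dimmest 2019 genes against 0.14 to 0.25 on the other arrays, but not in the brightest 2019 (0.26 against 0.25 to 0.29), and not with the processed signals (0.90 against 0.56 to 0.69 in the dimmest 2016).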
